A study of Homo sapiens with 4 samples.

How the data were processed

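Total RNA libraries from 4 dishes of HEK 293 cells were compared, 2 with a sup-tRNA plasmid and 2 with an empty vector, all lysed 48 h after transfection with Fugene6. Per the submitters' processing notes, the upstream tools were STAR 2.7.1a and DESeq2 1.40.1 with the GRCh38 build. The notes give the tools no roles, and the counting tool and annotation release are not given in the sources used here. The only deposited table is the authors' comparison of 2 groups. Its first measure is the authors' mean normalized signal per gene, a mean of normalized read counts over the libraries. The deposited log2 fold change and its standard error follow, then the authors' test score, the Wald statistic. The authors' p value and adjusted p value come last. Checked on the table itself, the score equals the log2 fold change over its standard error, and the adjusted p equals a Benjamini-Hochberg adjustment over the 5432 genes that have one. Adjusted p values that the authors left empty stayed empty. A mean of 0 and no p value was found for 20166 genes, and 41464 had a p value.

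The groups in the table are named by number only, so its signs could not be tied to the sup-tRNA or the empty vector. Because the table holds no value per library, no count test was run, replicates could not be compared or left out, and the depth per library is unknown. The means summed to 10997106 over all genes, of which MT-RNR2 held 9.91%, short noncoding RNA genes 18.8% and protein-coding genes 56.4%. The precision of each gene is given by the authors' standard error alone, with a median of 0.13 over genes with an adjusted p. Intervals in the plot are 95% normal intervals from it.

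Gene symbols were matched for 61552 IDs. Positions, biotypes and stop codons came from GENCODE release 29 on GRCh38, which held 57225 of the IDs and may differ from the authors' annotation, and tRNA genes came from RefSeq. The main transcript of a gene was the one with the longest coding sequence, which need not be the one these cells express. It gave the stop codon, GC content and length, with APPRIS principal transcripts as an alternative for the stop codon. Genes overlapping on the genome, near-identical copies and noncoding genes overlapping tRNA genes may share reads. Whether counting used strand is not given in the sources used here.

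The genes past an adjusted p of 0.05 were counted as the authors' deposited table gives them. For 27 gene lists, fixed before the data were examined, and for the 3 stop codon classes, the planned test was limma's camera on counts, and the plan said that no test would be run if the columns could not be matched to treatments. It could not be run. In its place limma's cameraPR was applied to the authors' deposited statistics, a choice made after the table had been seen. The main setting used genes with a mean normalized count of at least 50, 1 gene per symbol (13387 genes), a preset correlation of 0.01, two-sided p values and Benjamini-Hochberg adjustment over the 26 lists with at least 5 members, and separately over the 3 stop codon classes. These choices were set before any list result was seen. The test rests on 2 libraries per group, and its preset correlation could not be replaced by an estimated one, so 0.05 serves as a stricter preset. In all, 6 settings were run for the lists and 7 for the stop codons: the main one, the stricter correlation, ranks, a minimum mean of 10, genes with an adjusted p only, statistics adjusted for GC content and transcript length, and for stop codons also APPRIS transcripts. The adjustment for GC content and length was a weighted regression over coding genes.

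Named genes followed a rule fixed before the data were examined: the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold with a mean of at least 50, up to 4 members per list with the largest absolute change among those that passed or else the member with the smallest p, and 10 genes named in advance. Genes named outside it are said to be so, and 1 gene that the rule names is not reported here. The rule is also applied to 1 list added later. Bootstrap intervals of class medians used 10000 draws, or fewer for the largest class.

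Tested on simulated data, the gene counting step recovered 73% of genes changed by 0.5 log2 and 100% of those changed by 1 log2 among 5417 genes, with 10 false calls. The list test called 100% of 10 lists shifted by 0.25 log2 and 0% of 90 unshifted lists, with 30 members each, among 13387 genes. Both simulations drew each gene independently and took the authors' standard errors as true. They therefore say nothing about correlated genes or smaller shifts. The software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.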

Results

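Total RNA was sequenced from HEK 293 cells, an established human embryonic kidney line, 48 h after transfection in 10 cm dishes with 10 ug of plasmid. The plasmid either expressed a suppressor tRNA (sup-tRNA), a tRNA that inserts an amino acid at a stop codon, or was an empty vector. Per the labels there were 2 sup-tRNA and 2 control biological replicates. The stated question was how the sup-tRNA affects readthrough at native stop codons and gene expression. Ribosome footprint libraries of the same design were not analysed here. The values come from 1 table, the authors' own comparison, which gives for 61630 Ensembl genes a mean normalized count, a log2 fold change, its standard error and a p value. It holds no value per library, so the depth per library is unknown and no spread between replicates can be shown. The 2 groups in it are named only by number, and nothing in the sources used here says which of them received the sup-tRNA. Fold changes are therefore given as positive or negative, and neither sign is assigned to a treatment.

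In the authors' deposited table, 153 genes had an adjusted p under 0.05, of which 51 had a positive and 102 a negative fold change. HMOX1, the stress-inducible heme oxygenase, stood far from the rest at a log2 fold change of 3.31 (SE 0.14, adjusted p = 1.96e-116), a 9.90-fold difference. The next largest positive value among the genes past the threshold was 1.42, and the lowest negative value was -0.85. Only 4 of the genes past the threshold had an absolute log2 fold change of at least 1, and all 4 were positive (HMOX1, ERCC5, H1-3 and HSPA5). ERCC5 overlaps a readthrough gene model, BIVM-ERCC5, and may share its reads. The decoy death receptor TNFRSF10D was at 0.85 (SE 0.14) in the authors' deposited table. Of the positive genes 50 were protein-coding. The negative genes comprised 50 protein-coding genes, 38 short noncoding RNA genes and 14 other genes, 7 of which overlap an annotated tRNA gene. When genes that overlap on the genome were counted once, 49 positive and 93 negative loci remained. The authors' adjusted p covers 5432 genes, all with a mean normalized count of at least 372.8, and the other 36032 genes with a p value have none.

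**Figure D1:**
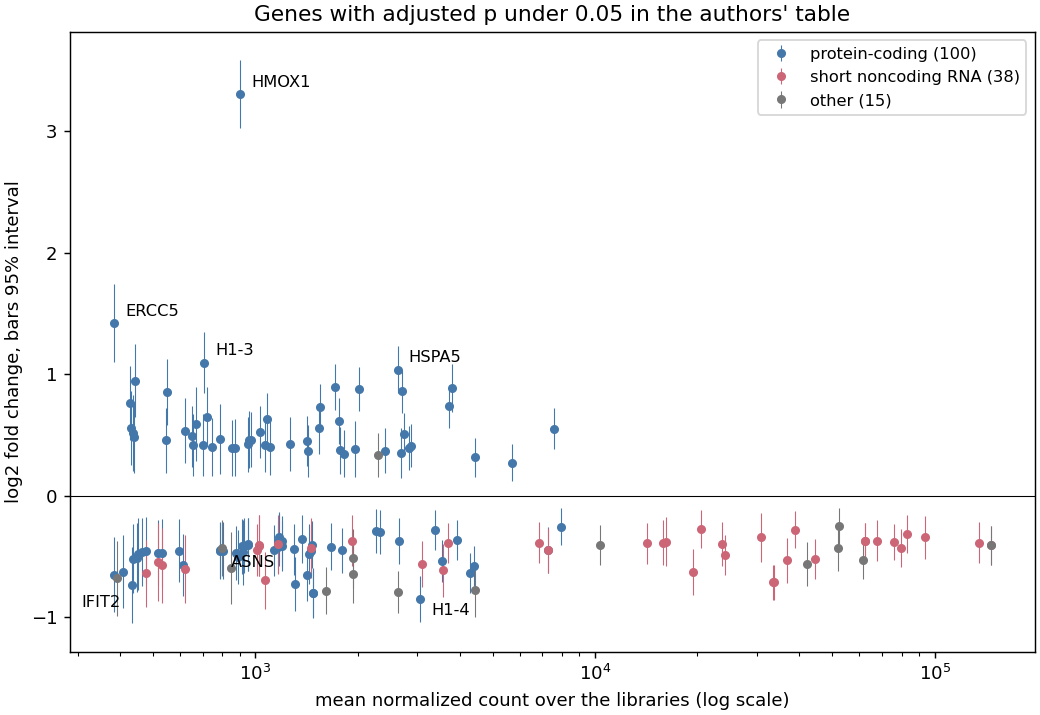
Log2 fold change against mean normalized count (log axis) for the 153 genes with an adjusted p under 0.05 in the authors' deposited table, with bars for the 95% interval from the authors' standard error and colours for protein-coding genes (100), short noncoding RNA genes (38) and other genes (15). HMOX1 lies at 3.31, the other positive genes reach 1.42, and all 38 short noncoding RNA genes lie below 0.

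Genes of the endoplasmic reticulum unfolded protein response, which encode chaperones and folding enzymes of the secretory pathway, lay on the positive side as a group. Of the 22 list members with an adjusted p in the authors' deposited table, 11 passed on the positive side and none on the negative side, and 8 further members had no adjusted p. Adjusted over the list alone, 18 of the 30 members passed, all positive. The median log2 fold change was 0.37, with 29 of the 30 above 0. The chaperone HSPA5 (BiP; chromosome 9, 125234853 to 125241330, GRCh38) had a log2 fold change of 1.04 (SE 0.10, adjusted p = 9.66e-23) in the authors' deposited table. There HERPUD1, a component of endoplasmic reticulum-associated degradation, was at 0.95, the chaperone HSP90B1 at 0.89 and the disulfide isomerase PDIA4 at 0.88. The test of the whole list against all other genes gave an adjusted p of 3.27e-48 (limma's cameraPR on the authors' deposited statistics, preset correlation 0.01) and 1.21e-25 with a preset correlation of 0.05.

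The cytosolic heat shock list was positive as a whole (20 genes compared, median log2 fold change 0.08, limma adjusted p = 4.21e-05), but few members carried it. HSPA1A (0.86) and HSPA1B (0.74) passed on the positive side of the authors' deposited table, and the HSP90 co-chaperone AHSA1 (-0.52, adjusted p = 0.0171) on the negative side. Adjusted over the list alone, 3 were positive and 1 negative. HSPA1A and HSPA1B are near-identical copies whose reads cannot be separated with certainty. With ranks in place of the statistic the limma adjusted p of this list was 0.0553, and with GC content and length adjusted its median was 0.04.

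Targets of ATF4 and the integrated stress response were negative as a list (37 genes, median log2 fold change -0.11, limma adjusted p = 0.00194), with an adjusted p of 0.0541 at a preset correlation of 0.05. Of the 27 members with an adjusted p in the authors' deposited table, 1 passed, ASNS, the asparagine synthetase, at -0.45 (SE 0.12, adjusted p = 0.00755). An overlapping gene model may share its reads. Adjusted over the list alone, 3 members were negative. ATF4 itself was at 0.09 (adjusted p = 0.861) and DDIT3 at 0.22 with no adjusted p in the authors' deposited table.

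Interferon-stimulated genes, which encode antiviral proteins, lay on the negative side. Of 43 genes compared, 42 were below 0, with a median log2 fold change of -0.44 (limma adjusted p = 1.73e-27, and 5.60e-13 with a preset correlation of 0.05). Of the 18 members with an adjusted p in the authors' deposited table, 5 passed, all negative, while 29 members had a p value and no adjusted p. Those that passed included IFIT2 at -0.74 (SE 0.16, adjusted p = 0.000411), IFI6 at -0.65, OAS3 at -0.48 and the ubiquitin-like modifier ISG15 at -0.46. Adjusted over the list alone, 22 members were negative and 0 positive. IFIT1 was at -0.67 with a large standard error (0.32) and an adjusted p of 0.369 in the authors' deposited table.

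Short noncoding RNA genes formed the largest noncoding group on the negative side. The fixed list of RNA polymerase III transcripts and spliceosomal RNAs had a median log2 fold change of -0.21 over 25 genes, 24 of them below 0 (limma adjusted p = 8.08e-32, and 3.28e-18 with a preset correlation of 0.05). Of its 24 members with an adjusted p in the authors' deposited table, 9 passed, all negative, and 12 did adjusted over the list alone. Genes with a vault RNA symbol led the list: VTRNA2-1 (chromosome 5, 136080470 to 136080597) was at -0.71 (SE 0.07, adjusted p = 7.73e-19), VTRNA1-1 at -0.63, VTRNA1-3 at -0.56 and VTRNA1-2 at -0.53 in the authors' deposited table. A second gene model, Vault, overlaps VTRNA2-1 and has nearly the same values. By class, the median log2 fold change of genes with a mean of at least 50 was -0.33 for 44 Y RNA genes, -0.32 for 22 mitochondrial tRNAs, -0.22 for 255 snoRNAs and -0.12 for 103 snRNAs, against 0.01 for 11541 nuclear protein-coding genes. Noncoding genes outside the short classes, of any biotype, that overlap a tRNA gene had a median of -0.47 (19 genes). Genes of long noncoding biotypes that overlap none had -0.03 (440 genes), so the 2 sets are not defined alike. The 3 unnamed genes among the largest negative values, ENSG00000259932 (-0.80), ENSG00000260035 (-0.78) and ENSG00000253190 (-0.78) in the authors' deposited table, overlap 1, 1 and 3 annotated tRNA genes.

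**Figure D2:**
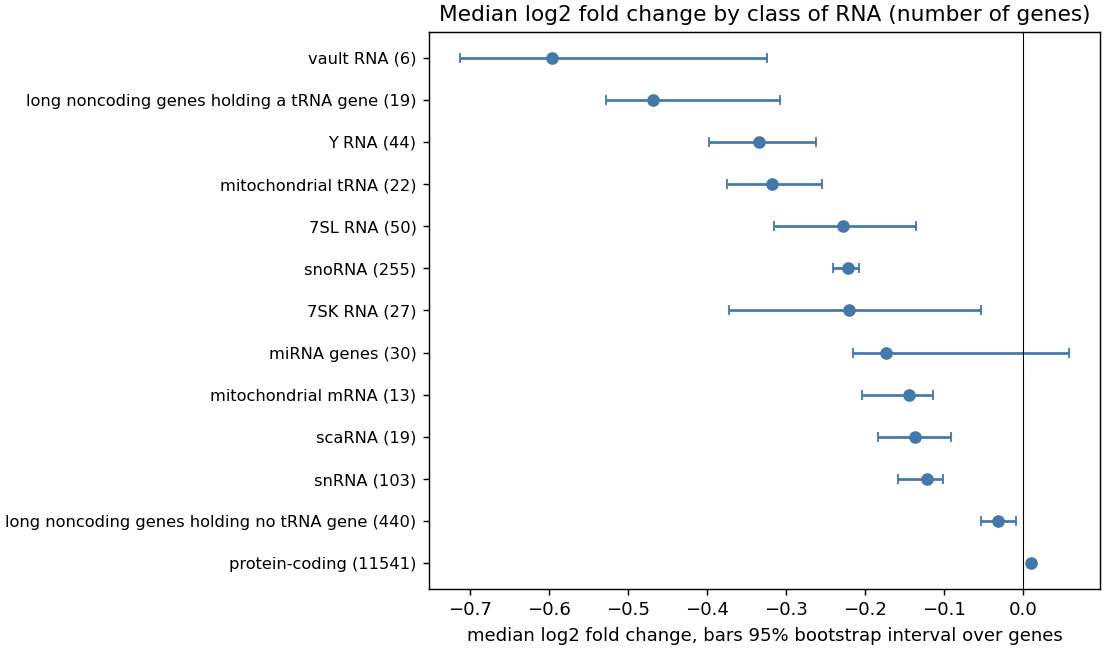
Median log2 fold change of each class of RNA, for genes with a mean normalized count of at least 50 (number of genes in brackets), with bars for the 95% bootstrap interval over genes, which are not independent replicates. All 9 classes of short RNA have a median below 0, and the interval of the miRNA genes reaches 0.06.

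Replication-dependent histone genes went both ways. By the authors' deposited table, 4 members of the fixed list passed on the positive and 4 on the negative side, and 6 and 7 did adjusted over the list alone. The linker histone H1-3 was at 1.10 (SE 0.13, adjusted p = 2.00e-15), whereas H1-4 was at -0.85 (adjusted p = 1.28e-15), H2AC13 at -0.73 and H1-2 at -0.63 in the authors' deposited table. H1-4, H2AC13 and H1-2 end in the stop codon UAG and H1-3 in UGA. The list test found no shift to one side (42 compared, limma adjusted p = 0.942), and it cannot see members that move both ways. With GC content and length adjusted the list passed on the positive side (limma adjusted p = 0.00501). H4C14 (-0.80) and H4C15 (-0.80) also passed on the negative side of the authors' deposited table. They are not in the list, so its counts and test leave them out. H4C14 and H4C15 are copies that may share reads. Each also overlaps an H3 gene with nearly the same mean count and may share its reads. The means were 1482.6 for H4C14 and 1487.8 for H3C14, and 1476.7 for H4C15 and 1485.6 for H3C15.

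Several metabolic and translation lists were shifted by small amounts. Mitochondrially encoded mRNA and rRNA genes were all below 0 (15 genes, median -0.16, limma adjusted p = 1.46e-07), although 0 of the 15 passed in the authors' deposited table and 3 did adjusted over the list alone, and MT-ND3 was at -0.33 (adjusted p = 0.0580). Of the 22 mitochondrial tRNA genes, which are not in that list, 21 were below 0, and 11 of the 21 with an adjusted p in the authors' deposited table passed, all negative. Cytosolic ribosomal proteins had a median of -0.05 over 77 genes (limma adjusted p = 2.40e-05), with RPL37A (-0.58), RPL32 (-0.42) and RPS19 (-0.26) past the threshold in the authors' deposited table and the same number adjusted over the list alone. RPL37A, RPL32 and RPS19 all end in the stop codon UAG, a group taken up below. Cholesterol synthesis genes and SREBP2 targets had a median of -0.14 over 28 genes (limma adjusted p = 3.28e-05), INSIG1 (-0.45) and SCD (-0.28) passing in the authors' deposited table and 4 genes adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes had a median of -0.08 (54 genes, limma adjusted p = 0.00223, and 0.0847 with a preset correlation of 0.05). None of them passed in the authors' deposited table or adjusted over the list alone, NDUFS7 coming closest at -0.41 (adjusted p = 0.0599).

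Translation termination and ribosome rescue factors, the list closest to stop codon reading, had a median log2 fold change of 0.07 over 28 genes (limma adjusted p = 0.0188, and 0.114 with a preset correlation of 0.05). Both in the authors' deposited table and adjusted over the list alone, 1 member passed, the ribosome rescue factor HBS1L at 0.46 (SE 0.12, adjusted p = 0.00447). The release factors ETF1 (0.21, adjusted p = 0.407) and GSPT1 (0.09, adjusted p = 0.854) and the decay factor UPF1 (0.04, adjusted p = 0.951) did not pass in the authors' deposited table. Substrates of nonsense-mediated decay had a median of 0.05 over 56 genes and missed the threshold (limma adjusted p = 0.0518). They held 1 positive gene, CLK1 (0.56), in the authors' deposited table and the same number adjusted over the list alone. With GC content and length adjusted, the limma adjusted p was 0.00447, but over 46 coding members only. The 2 values are for different gene sets, so the gain cannot be credited to the adjustment alone. GAS5, a noncoding substrate of nonsense-mediated decay, was at -0.16 in the authors' deposited table (adjusted p = 0.546). Genes with readthrough described in the literature did not differ from other genes (18 genes, median 0.00, limma adjusted p = 0.942), AMD1 coming closest at 0.26 (adjusted p = 0.187) in the authors' deposited table.

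**Figure D3:**
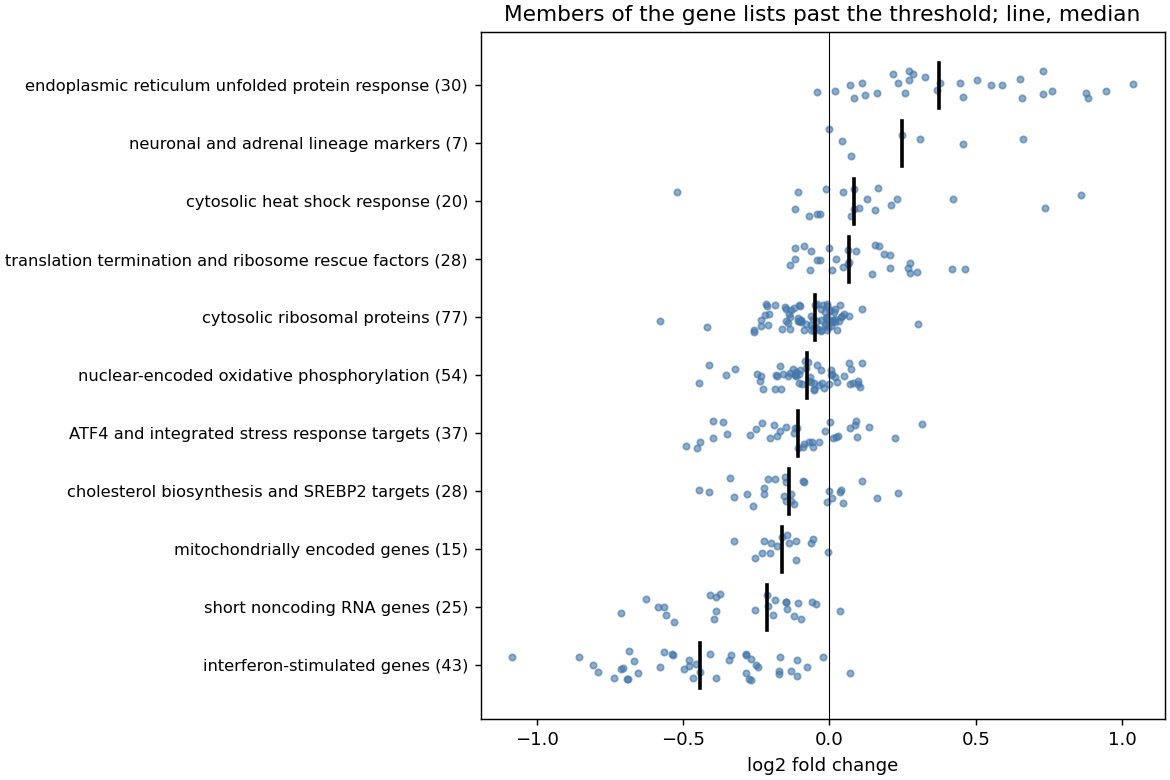
Log2 fold change (x axis) of each member with a mean normalized count of at least 50 (points, number in brackets) in the 11 gene lists with a limma adjusted p under 0.05, with a line at each median. The unfolded protein response list has a median of 0.37 and the interferon-stimulated genes one of -0.44, while the ribosomal proteins have a median of -0.05.

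Markers of other cell types gave 1 shifted list in the main setting. Neuronal and adrenal markers, some of which HEK 293 cells express, had a median of 0.25 over 7 genes (limma adjusted p = 0.0461, and 0.0909 with a preset correlation of 0.05), INA being at 0.46 with no adjusted p in the authors' deposited table. Renal epithelial (adjusted p = 0.161) and fibroblast markers (0.948) did not pass in the limma test, and EPCAM (0.38, adjusted p = 0.143) and VIM (-0.12, adjusted p = 0.682) did not in the authors' deposited table. With GC content and length adjusted, the renal markers passed (limma adjusted p = 0.0294). Only 1 blood cell marker had a mean of at least 50, so that list was not tested.

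The other lists did not pass the limma test in the main setting. With GC content and length adjusted, mitotic genes (limma adjusted p = 0.00501, negative) and immediate early genes (0.0457, positive) did. In the main setting the adjusted p was 0.182 for mitotic genes, 0.233 for p53 targets, 0.233 for immediate early genes, 0.390 for cytosolic aminoacyl-tRNA synthetases, 0.530 for the RNA polymerase III machinery, 0.560 for hypoxia and glycolysis, 0.755 for DNA replication, 0.851 for the proteasome, 0.879 for nuclear retained RNA and 0.886 for NF-kB and inflammation. The median and the mean statistic had opposite signs for hypoxia and glycolysis, nuclear retained RNA and fibroblast markers. A single immediate early gene passed in the authors' deposited table, EGR1 at 0.59 (adjusted p = 0.00832). AARS1, the alanyl-tRNA synthetase, was at -0.15 (adjusted p = 0.669) and CDKN1A at 0.07 (adjusted p = 0.866) in the authors' deposited table.

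Grouped by the stop codon of their main transcript, genes ending in UAG lay slightly below other coding genes. Their median log2 fold change was -0.03 over 2483 genes, against 0.02 for the other coding genes (limma adjusted p = 0.0101). The median was 0.04 for 3334 genes ending in UAA (adjusted p = 0.0577) and 0.01 for 5683 ending in UGA (adjusted p = 0.776). The UAG shift was lost with a preset correlation of 0.05 (limma adjusted p = 0.520), and the correlation between genes cannot be estimated without values per library. For a class of 2483 genes the outcome depends heavily on the preset, so these settings do not decide whether the shift holds. Among genes past the threshold in the authors' deposited table, 33 UAG genes were negative and 10 positive, compared with 4 and 16 for UAA and 13 and 24 for UGA. Which stop codon the sup-tRNA reads is not stated in the sources used here.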

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

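No paired analysis was possible because the table holds no values per library. For the same reason the settings for counts chosen before the data were examined were not run: other normalizations and filters of the counts per library, the replicate block, leaving out each replicate, other count tools, a count test against a minimum fold change, an estimated correlation and fry. The alternatives for gene lists and stop codons, and those on the range of the adjustment, overlapping genes and gene classes, were chosen after seeing the data. The authors' count of 153 genes fell to 4 (4 positive, 0 negative) with an absolute log2 fold change of at least 1, and to 86 (43 positive, 43 negative) among protein-coding genes with no short RNA gene inside them, fewer genes being eligible in each case. At an adjusted p under 0.1 it was 217, and the positive genes went from 51 to 80. With the adjustment recomputed over genes with a mean of at least 50, at least 10, or over all genes with a p value, 138, 138 and 113 genes passed, of which 117, 114 and 94 were among the 153. A minimum mean of 50 removed none. Of the 26 lists tested, 11 passed in the main setting and 7 with a preset correlation of 0.05, which lost the ATF4, oxidative phosphorylation, termination and neuronal lists, since a larger correlation widens the test's error. Between 9 and 15 passed in the other settings, not all of which could test every list. The NF-kB, neuronal, fibroblast and renal lists had too few members among genes with an adjusted p. The setting adjusted for GC content and length covers coding genes only. In it the short noncoding and nuclear retained RNA lists have no test, and the decay substrates keep 46 of 56 genes. Ranks lost the heat shock and termination lists, and the termination list was also lost among genes with an adjusted p. With GC content and length adjusted, the decay substrates, histones, immediate early genes, mitotic genes and renal markers passed as well, and decay substrates did with a minimum mean of 10. No list or stop codon class that passed in either of the settings compared changed direction, but 4 lists that passed in none did so around 0: NF-kB and inflammation, readthrough genes, hypoxia and glycolysis, and nuclear retained RNA. Of the stop codon classes 1 passed in the main setting, 0 with a preset correlation of 0.05, and 2 (UAG and UAA) with ranks, among genes with an adjusted p, and with APPRIS transcripts; the cause was not tested. With GC content and length adjusted, UAG passed (adjusted p = 0.0338, limma) and UAA had an adjusted p of 0.602, its difference in mean statistic going from 0.23 to 0.05. Low genes are limited by the authors' filter: 24 genes without an adjusted p would pass with an adjustment over genes with a mean of at least 10.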

Other observations

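The tests on pseudogenes, overlapping genes, NRF2 targets and the stop codons of single genes were chosen only after the results they bear on had been seen. Genes below the range of the authors' adjustment included some of the largest differences, and are named here after their values were seen. The largest in the authors' deposited table, among those that would pass an adjustment over genes with a mean of at least 10, was SLC5A10 at a log2 fold change of 4.24 (SE 0.99) and a mean normalized count of 19.5. It overlaps FAM83G, which has a mean of 647.8 in the authors' deposited table and may share its reads. The lowest there were IRS3P at -2.70 (mean 36.1) and ENSG00000289046 at -2.30 (mean 81.2) in the authors' deposited table. The stress-inducible HSPA6 was at 3.18 (mean 32.6) and its copy HSPA7 at 3.19 in the authors' deposited table. ZCCHC12 was at 1.12 and ACTN2 at 1.21, while the interferon-stimulated genes OAS2 (-1.09), RSAD2 (-0.86) and IFITM1 (-0.81) extended the negative group in the authors' deposited table. None has an adjusted p there.

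Stop codons of the genes past the threshold were uneven, a count noticed after the values were seen. Of the 50 protein-coding genes with a negative fold change, 33 (66.0%) ended in UAG, against 1048 of the 4981 coding genes with an adjusted p (Fisher's exact test, two-sided, odds ratio 7.49, adjusted p = 4.15e-11 over 6 tests of 3 codons in 2 directions). Of the 50 positive genes 10 ended in UAG (adjusted p = 1.00, the same exact test). Among the 33 negative UAG genes were AHSA1, ASNS, RPL37A, RPL32 and RPS19. They are every negative gene past the threshold in the heat shock, ATF4 and ribosomal protein lists. The positive HSPA1A and HSPA1B also ended in UAG, whereas the negative INSIG1, SCD and IFIT2 ended in UGA. Without the members of all fixed lists the negative share was 23 of 34 (adjusted p = 4.41e-08, the same exact test). Permuting stop codons gave p = 0.0001, the smallest that 10000 permutations can give, both without the genes past the threshold (mean log2 difference -0.05, UAG minus others) and without list members within bins of GC content, length and mean count. Within bins the difference was -0.048, against a mean of -0.011 over the permutations, so part of it follows from the binned traits. The permutation without the genes past the threshold used no bins. These tests treat genes as independent, which they are not: several histone genes here are copies. ASNS, H4C14, H4C15 and, chosen after their values were seen, NDUFA13, RNASEH2A and PLCG2 overlap other gene models. The list test that allows for correlation kept the UAG class at a preset of 0.01 and lost it at 0.05. For a class of this size its outcome depends heavily on the preset, so it cannot decide the question. With GC content and length adjusted, the class kept an adjusted p of 0.0338 in the limma test, and its difference in mean statistic went from -0.33 to -0.27. Other explanations for the UAG count were not tested, and with the sign of the comparison unassigned it cannot be read as a gain or loss with the sup-tRNA.

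Endoplasmic reticulum chaperone genes on the positive side were weighed against GC content and against shared reads. Across coding genes log2 fold change fell with GC content (Spearman's rho -0.32 over 11552 genes, which are not independent), but after regression on GC content and length the list's median was still 0.36. Its 26 members with no pseudogene of their symbol in the table had a median of 0.35, so reads shared with pseudogenes of the same symbol do not account for the list. Pseudogenes under other symbols were not examined. A response in the cells of one group remains a hypothesis, since it was found and tested in the same table and differences between dishes could not be examined.

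Short noncoding RNA genes on the negative side were not 1 signal counted at overlapping genes, because 35 loci passed after such genes were collapsed. Reads shared by similar copies at other positions were not examined, so these loci need not be separate signals. A lower share of all short RNA in the libraries of one group, from RNA isolation or library preparation, may account for the negative short RNA genes. All 9 classes had a median below 0, the highest being -0.12, although the interval of the miRNA genes reached 0.06. Mitochondrial tRNAs are among these classes, and the same would extend to longer noncoding genes that overlap a tRNA gene. A change in transcription by RNA polymerase III is open too, as untested, but mitochondrial tRNAs and most snoRNAs are not made by that enzyme.

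Interferon-stimulated genes on the negative side kept a median of -0.43 after adjustment for GC content and length. The 38 members that overlap no gene of at least their own mean had a median of -0.45. Neither explanation accounts for the list, and a difference between the groups in the response to the transfected plasmid or its RNA is a hypothesis that these values do not test. Differences between single dishes remain open.

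HMOX1, a target of the regulators NRF2 and BACH1, had the largest positive fold change among genes with an adjusted p, and a shared rise of their targets was tested as a hypothesis on a list chosen after HMOX1 was seen. With HMOX1 in the list, limma's test on the statistics of the authors' deposited table gave p = 0.0215 for the list, but this result rests on HMOX1 itself, and the list's median was -0.06. Without it, the mean statistic of the 22 other targets was -0.43, against 0.01 for other genes (permutation p = 0.0683), and 16 of the 22 lay below 0. The difference at HMOX1 was thus not shared by the other targets.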
